A study of Pyrus communis with 6 samples.

How the data were processed

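Gene expression was measured in the receptacle of European pear (Pyrus communis), the floral tissue below the petals that later becomes the flesh of the fruit. The labels give 2 cultivars, 'La France' and 'Giant Laf'. The second arose from the first as a bud mutant, a shoot that carries a somatic mutation and is propagated as a line of its own. Flower buds were taken 1 week before full bloom in 2010, and the receptacle was cut out of them by laser microdissection. Each cultivar had 3 arrays, which the series design describes as biological replicates. How many trees they came from is not given in the sources used here. Per the labels' protocols, total RNA was extracted with a kit for very small samples and amplified and labelled with Cy3 by a 1-colour low-input procedure. Each RNA was hybridised to its own array.

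The deposited scanner files were made with Agilent Feature Extraction 10.7.1.1, per the file headers. They hold, for each spot, an intensity that is already background-subtracted and detrended (the processed signal), and the median pixel intensity of the spot and of its local background, per the file headers. These intensities are not normalized between arrays. The files also carry flags for outlier spots, saturated spots and spots well above background. The authors deposited a table of log2 values as well, with 1 value per probe and array. The labels do not state how it was made, so it was set against the scanner signal of the same arrays. In each of its columns the 75th percentile lay within 0.001 of 0. Between 99.738% and 99.747% of its values equalled the log2 mean processed signal of the probe's spots minus 1 constant per array, with a tolerance of 0.001. The others departed by up to 2.86 log2 units, and the reason is not given in the sources used here. The medians of the columns were -2.41, -2.37 and -2.46 for Giant Laf and -2.48, -2.52 and -2.53 for La France, in replicate order. This table served as an alternative only.

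Each array held 21681 probes besides controls. Of these, 21666 were printed as 2 spots and 15 as 10 spots. The log2 processed signals of a probe's spots were averaged after leaving out spots with an outlier flag, of which the arrays had 31 to 118. No spot was saturated. The 75th percentile over all probes was then subtracted from each array. A probe counted as well above background on an array where at least a share of 0.5 of its spots carried that flag. The 16339 probes well above background on at least 3 of the 6 arrays, whatever the cultivar, were tested, and 5342 were not.

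Differences between the cultivars were tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with cultivar as the only term and a two-sided test. Benjamini-Hochberg adjusted p-values below 0.05 counted as calls. Fold changes are Giant Laf minus La France on the log2 scale, and confidence intervals are at 95%. Similarity of the arrays was the mean Pearson correlation of pairs within a cultivar minus that between cultivars, tested by exact permutation over the 10 splits of 6 arrays into 3 and 3, where the smallest possible p is 0.1. For a probe well above background on every array of one cultivar and on none of the other, a fold change is a lower bound. This bound concerns background only and leaves out the spread between arrays. It was computed from the bright cultivar's mean against the dim cultivar's mean of, per array, the lowest signal among probes well above background or the probe's own signal, if higher. The precision of all values is limited by the number of arrays.

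The tests, the groups, the alternatives, the rule for named probes and 25 gene lists were fixed before the data were examined. The lists were word patterns for gene descriptions, covering cell cycle, DNA replication, histones, mitosis, cell wall, aquaporins, hormones, floral identity, organ size, photosynthesis, flavonoids, sugars, stress, ribosome, proteasome and markers of neighbouring tissues. The files do not pair the probe identifiers with genes or descriptions. A reference table of 42167 pear genes, of the assembly drPyrComm1.1, matched 0 of the 21681 identifiers. No list could therefore be tested with these sources, and no gene is named. The 855 probes whose identifiers have the form of sequence accessions were not looked up elsewhere. The rule for named probes was to name annotated probes and the 5 of smallest p. Without annotation, the text is limited to 2 probes per direction, those of smallest p. Of the 5 of smallest p, 4 were higher in Giant Laf and 1 was lower, so 2 of them are not named. The second lower probe, NFR2_27_63mR2007a, lies outside the rule and was chosen after its values were seen.

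The test was tested on simulated data, with 10 runs of 16339 independent probes whose variances were drawn from the fitted distribution. It recovered 50% of 100 probes changed 2-fold and 88.5% of 100 changed 4-fold, with 8.4 false calls per run on average. With no probe changed, it made 0 calls on average and gave a mean of 822.2 probes with an unadjusted p below 0.05, at most 869 in a run. The simulation leaves out correlation between probes. Each run also held 200 changed probes together. With fewer changed probes, the Benjamini-Hochberg adjustment asks for a smaller p. The recovered shares therefore hold for that number of changed probes and do not give the sensitivity in these data.

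The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, other filters on dim probes, the deposited log2 table, a variance trend with robust estimation, array weights, the replicate number or the slide as a block, a plain test per probe, and leaving out each array. The planned normexp used mean pixel intensities. These are not used here, and median pixel intensities took their place. The headers place the 3 Giant Laf arrays and La France replicate 1 on 1 slide, and La France replicates 2 and 3 on another. Slide could therefore be fitted as a term, although the slide effect rests on La France alone.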

Results

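The receptacle of 'Giant Laf' was compared with that of its parent cultivar 'La France' on 6 single-colour oligonucleotide arrays, 3 biological replicates per cultivar. The comparison asks which transcripts differ between a bud mutant and the cultivar it arose from, in the same tissue and at the same stage, 1 week before full bloom. The 75th percentile of the processed signal was 1639, 1202 and 1021 on the Giant Laf arrays and 799, 1336 and 927 on the La France arrays, in replicate order. On the log2 scale this was 10.30 ± 0.35 for Giant Laf and 9.96 ± 0.38 for La France (mean ± SD, n = 3 each). Between 73.9% and 77.2% of the 21681 probes were well above background on each array. The SD of a single spot within an array was 0.070 to 0.090 log2 units, estimated from the median absolute difference between paired spots of a probe. Spike-in RNAs gave a slope of signal on amount between 1.00 and 1.03.

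The receptacle profiles of both cultivars were close to each other. Over the 16339 tested probes, the mean Pearson correlation was 0.986 between arrays of one cultivar and 0.983 between arrays of different cultivars. The difference of 0.00324 was the largest of the 10 splits of the arrays, with 0.00281 in the next, in which the replicate 3 arrays of the cultivars change places, and the exact permutation p of 0.1 is the smallest this design allows. Without the filter on dim probes the difference was 0.00157 and the exact permutation p was 0.2, so the cultivars were no longer the first of the splits. La France replicates 1 and 2 were the most alike, with r = 0.9915. The replicate 3 arrays of the 2 cultivars came next, with r = 0.9906, above the 0.9860 and 0.9806 of Giant Laf replicate 3 with the other Giant Laf arrays. On the first principal component, which held 38.6% of the variance, Giant Laf replicates 1 and 2 scored 23.7 and 40.5 and La France replicates 1 and 2 scored -36.2 and -28.8. Both replicate 3 arrays lay between them, at 1.17 for Giant Laf and -0.38 for La France. They stood apart on the second component (26.2%), at 34.3 and 26.4, where the other 4 arrays were negative.

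**Figure D1:**
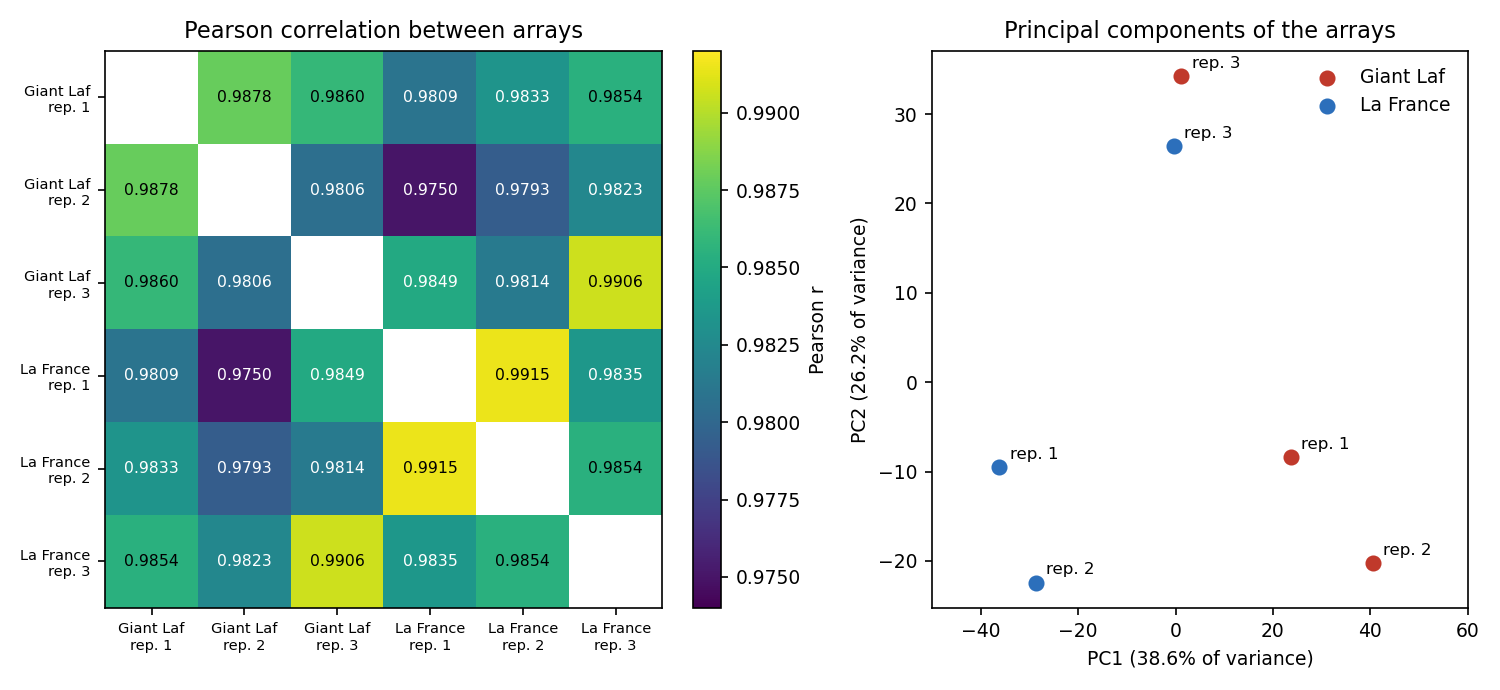
Left, Pearson correlation of log2 signal between each pair of the 6 arrays over 16339 probes, with the diagonal left blank. Right, scores of the arrays on the first 2 principal components (38.6% and 26.2% of the variance), coloured by cultivar; replicates 1 and 2 separate by cultivar along the first component, and both replicate 3 arrays lie near 0 on it.

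No probe differed between Giant Laf and La France at a Benjamini-Hochberg adjusted p below 0.05 in limma, and the smallest adjusted p was 0.211, shared by 3 probes. An unadjusted p below 0.05 was reached by 2612 probes (16.0%), where 817 would be expected by chance on average. The other splits of the arrays, examined only after the result was seen, gave 106 to 1753 such probes. A plain two-sample test of each probe on the same values gave 0 calls after adjustment and 2135 probes at an unadjusted p below 0.05. The limma count was 1524 without La France replicate 2, 1553 without Giant Laf replicate 2, 1664 without Giant Laf replicate 1 and 1713 without La France replicate 1. The count rose to 3114 without Giant Laf replicate 3 and to 3705 without La France replicate 3. It was 4284 with array weights and 4125 without both replicate 3 arrays, a setting chosen after the data were seen. Of the 2612 probes, 1737 were higher and 875 lower in Giant Laf. Among them, 174 were at least 2-fold higher and 66 at least 2-fold lower. In 3646 probes (22.3%) the 3 arrays of one cultivar all lay above the 3 of the other, where chance gives 10% on average. Of these, 2273 were higher in Giant Laf and 1373 lower. These splits depend on the scaling: with median centring, 955 probes at an unadjusted p below 0.05 were higher and 1748 lower, 122 and 115 of them at least 2-fold, and 1252 probes without overlap were higher and 2562 lower. The more frequent direction thus turned in the first and last of these counts.

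The probe of smallest p was NFW2_07_21cc. Its log2 signal relative to the 75th percentile was -6.46 ± 0.20 in Giant Laf and -4.68 ± 0.16 in La France (mean ± SD, n = 3 each), 3.43-fold apart with Giant Laf the lower. The log2 difference was -1.78 with a standard error of 0.15 (95% interval -2.14 to -1.42, adjusted p = 0.211 in limma). It was well above background on 2 Giant Laf and 3 La France arrays. NFR6_10_06tc was 2.53-fold higher in Giant Laf, at -3.53 ± 0.09 against -4.87 ± 0.19, a log2 difference of 1.34 with a standard error of 0.13 (interval 1.02 to 1.65, adjusted p = 0.211 in limma). NLE2_09_03tc was 3.43-fold higher in Giant Laf, at -5.18 ± 0.19 against -6.95 ± 0.27, a difference of 1.78 with a standard error of 0.18 (interval 1.36 to 2.20, adjusted p = 0.211 in limma). It was well above background on all 3 Giant Laf arrays and on 1 La France array. NFR2_27_63mR2007a was 2.03-fold lower in Giant Laf, at -5.17 ± 0.15 against -4.15 ± 0.20, a difference of -1.02 with a standard error of 0.15 (interval -1.37 to -0.67, adjusted p = 0.256 in limma). For each of these probes the 3 arrays of one cultivar lay apart from the 3 of the other, and none passed the adjusted threshold. The probes were picked for their small p, so this separation was largely fixed by the choice. The intervals make no allowance for that choice, which tends to overstate the differences. With normexp background correction the log2 differences were -0.59, 0.64, 0.23 and -0.46, in the order given.

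**Figure D2:**
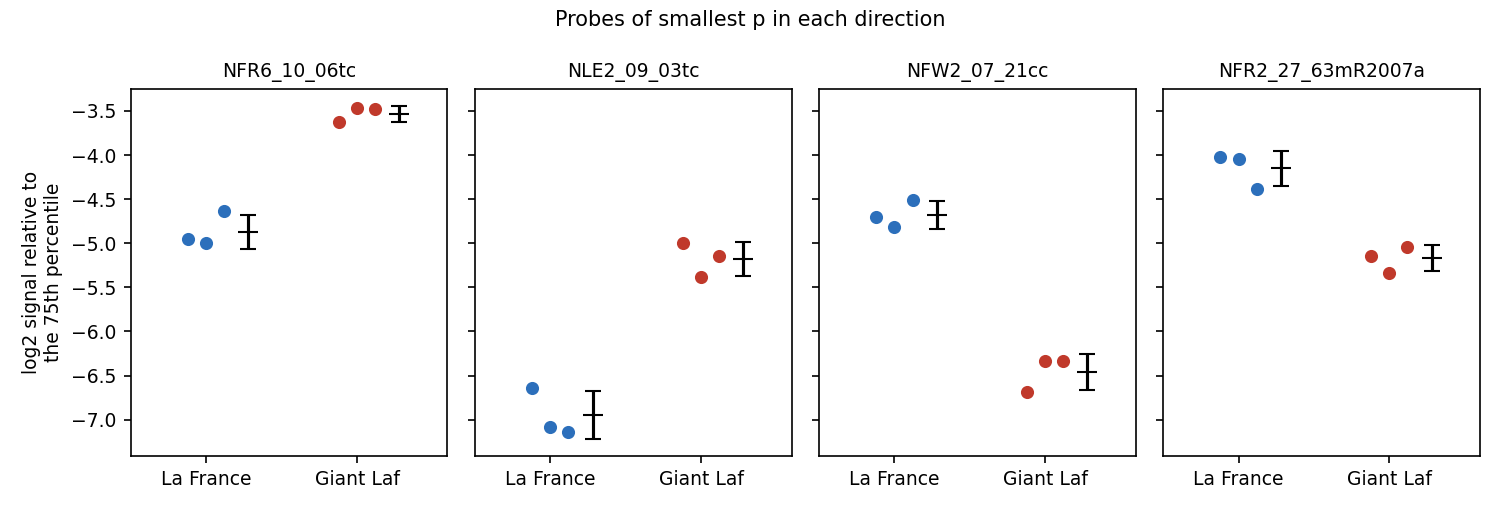
Log2 signal relative to each array's 75th percentile for the 2 probes of smallest p in each direction. Points are single arrays, 3 per cultivar, and the black bars beside them are the mean and SD. In each probe, picked for its small p, the cultivars do not overlap. The adjusted p in limma is 0.211 for the first 3 and 0.256 for the last.

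Probes whose identifiers share a stem and differ in their ending had similar differences. Among 6795 such pairs, the log2 differences between cultivars correlated with r = 0.730 and Spearman's rho = 0.680 across pairs, which are not independent replicates, and 78.3% had the same sign. In the 4056 pairs with mean signals within 1 log2 unit of each other, r was 0.895 and 87.5% had the same sign. In the 1699 pairs with the widest gap in mean signal, r was 0.431 and 61.7% had the same sign. Both probes of a pair reached an unadjusted p below 0.05 in 573 pairs, and 562 of these (98.1%) had the same sign. The tested partner of NFR6_10_06tc was higher in Giant Laf by 1.82 on the log2 scale, that of NLE2_09_03tc was higher by 0.775, and that of NFR2_27_63mR2007a differed by -0.98, each at an unadjusted p below 0.05 in limma. NFW2_07_21cc had no tested partner. The files do not say whether such probes target the same transcript.

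Over all tested probes the median log2 difference was 0.024, with quartiles of -0.159 and 0.212 and a median standard error of 0.150. The median SD within a cultivar was 0.162 in Giant Laf and 0.175 in La France. At least a 2-fold difference, whatever the p, was seen in 247 probes higher and 132 lower in Giant Laf, 2.32% of those tested. Of the 20 probes with the widest difference, from 1.86 log2 units upwards in size, 16 had overlapping cultivars and 7 reached an unadjusted p below 0.05, and their median SD within a cultivar was 1.64.

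With the arrays scaled to the 75th percentile, the direction of the small differences varied with signal level. With the tested probes in 5 classes of equal size by mean signal, the median log2 difference, Giant Laf minus La France, was 0.068 in the dimmest class, 0.094 in the next and -0.046 in the brightest. After quantile normalization these medians were -0.0075, -0.0095 and 0.010, each of the opposite sign. After cyclic loess normalization they were 0.037, -0.0021 and 0.0050, so that the dimmest class kept its sign. With the arrays scaled to the 75th percentile, the median log2 difference over the 500 brightest probes was -0.17. However, their median deviation from the mean of all arrays was -0.296 on Giant Laf replicate 1 and 0.113 on Giant Laf replicate 3. Of the probes at an unadjusted p below 0.05, 66.5% were higher in Giant Laf. This share was 56.2% after quantile normalization, 56.0% after cyclic loess normalization and 35.3% after median centring. With slide as a block, 1572 probes reached an unadjusted p below 0.05 and 51.1% of them were higher. Within slide 1, which held 3 Giant Laf arrays and 1 La France array, 1999 probes did and 48.3% were higher. Both estimates of the cultivar difference rest on La France replicate 1 alone, and within slide 1 that array was assumed to vary like the Giant Laf arrays, so no direction is read from these shares. Slide 2 held La France arrays only and gives no value of its own.

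**Figure D3:**
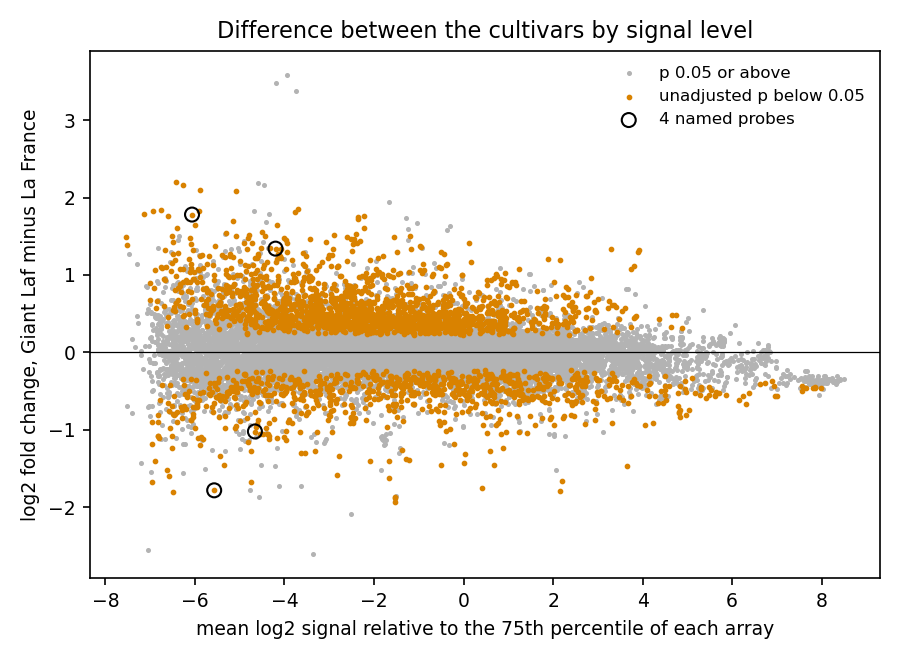
Log2 difference between Giant Laf and La France against mean log2 signal for the 16339 tested probes, with the 2612 at an unadjusted p below 0.05 in orange and the 4 named probes circled. The cloud narrows towards bright probes and lies below 0 for the 500 brightest, whose median is -0.17; that median was 0.0076 after quantile and -0.021 after cyclic loess normalization.

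Of the tested probes, 34 were well above background in one cultivar alone, and these overlap in part with the probes counted before. Of these, 30 were well above background on all 3 Giant Laf arrays and on no La France array, and 4 on all 3 La France arrays and no Giant Laf array. For such probes the fold is a lower bound with regard to background only, and the spread between arrays is left out. The median bound was 1.87-fold for the 30 probes and 2.22-fold for the 4. The widest bounds were 4.6-fold, higher in Giant Laf, and 2.64-fold, higher in La France. Each of these widest bounds equals the measured ratio of the cultivar means. None passed the adjusted threshold in limma, where the smallest adjusted p was 0.256 in each direction. The arrays differed in how many probes the scanner software marked. When the 16028 brightest probes of each array were counted in place of that mark, 16 probes stood out in Giant Laf alone and 16 in La France alone.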

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

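Cyclic loess, slide 1 alone, leaving out both replicate 3 arrays, averaging probes of one stem and the count at an unadjusted p were chosen only after the result was seen. The count of 0 probes past the adjusted p, with or without a 2-fold minimum, was the same under all 21 alternatives except the one without La France replicate 3. Leaving out single arrays gave 0 to 1 probes, and 0 to 1 at least 2-fold. The 1 probe, at adjusted p = 0.0496 in limma, was none of the 4 named and had adjusted p = 0.34 with all arrays. Its log2 difference, Giant Laf minus La France, was 5.47 without La France replicate 3 and 3.48 with all arrays. Elsewhere the smallest adjusted p ranged from 0.0796 with array weights to 0.53. The count at an unadjusted p below 0.05 ranged from 1524 to 3705 over single arrays left out. It was 1524 without La France replicate 2, 1553 without Giant Laf replicate 2, 1664 without Giant Laf replicate 1 and 1713 without La France replicate 1. Without Giant Laf replicate 3 it was 3114, and without La France replicate 3 it was 3705. It was 4284 with array weights, 1572 with slide as a block, 4125 without both replicate 3 arrays and 1392 with probes of one stem averaged, which leaves 9544 features (14.6%). Apart from the last, the cause was not tested. The replicate block gave 0 calls and 2395 probes at an unadjusted p below 0.05. Deviations of same-numbered arrays correlated at 0.015, 0.195 and 0.133, and those of arrays with different numbers at up to 0.191. Of the 6 arrays, 3 correlated best with their own number. With 1 value below 0.1, the numbers were not taken to pair the samples. The 4 named probes kept their direction under each of the 19 or 20 alternatives that measured them, with adjusted p from 0.0691 to 0.709 in these tests. Their cultivars did not overlap, so leaving out arrays, weighting them or refitting the same values could not turn the direction. Only alternatives that change the values or their scaling could have done so. The similarity difference stayed above 0, at 0.00342 with Spearman correlation, 0.00157 without a filter (exact permutation p = 0.2 against 0.1) and 0.00315 after quantile normalization. The alternatives for gene lists were not run, since no list had members. In dim probes, signal over background limits the fold.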

Other observations

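Of the tests below, the splits of the arrays, the brightness and signal-level tests of the surplus of small p-values, the exchange of labels, the correlation of same-numbered arrays, the classes of identifiers, the held-out pairs over all splits and the counts on single arrays were chosen only after the result was seen.

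Probe identifiers fall into classes by their first letters, whose meaning the files do not give, and 1 class has the form of sequence accessions. Of 8 classes with at least 30 tested probes, 2 were lower in Giant Laf than the other probes by limma's camera with a preset correlation. The 210 probes starting with DITNO had a median log2 difference of -0.166 (adjusted p = 0.000399), and the 55 starting with DITK had -0.232 (adjusted p = 0.00638). Neither call held with an estimated correlation, where the adjusted p was 0.781 for both. The other 6 classes had adjusted p of 0.497 or above, with 0.544 for the 390 tested probes of accession form (median log2 difference 0.0616). On single arrays, Giant Laf replicate 2 had 17 probes at least 4-fold above each of the other 5 arrays, up to 45.2-fold, and La France replicate 3 had 9, up to 13.5-fold. La France replicate 1 had 1 such probe and the other arrays 0. Giant Laf replicate 3 had 14 probes at least 4-fold below each of the other 5 arrays, against 0 to 6 on the others. When 500 probes were picked on 2 arrays per cultivar, a mean of 66.9% kept their sign in the pair left out (53.6% to 86.0%). The highest mean for another split was 68.5%, and 3 of the 10 splits, the cultivars included, gave at least as much.

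The surplus of small p-values, 2612 probes against 817 expected and at most 869 in simulations of independent probes, was weighed against slide, brightness and a trend with signal level. Brightness as the whole cause is argued against by the split with the widest brightness gap, 0.60 log2 units, which gave 1341 probes, and a signal-level trend by the 2548 left after cyclic loess. Slide stays a candidate explanation. With slide as a block, 1572 probes were left. In probes picked without La France replicate 1, the held-out pairs on slide 1 differed in the picked direction by a mean of 0.178 log2 units. They ranged from 0.0846 to 0.282 (SD 0.0993, n = 3), all above 0. The mean lay within 2 SD of 0. However, all 3 pairs share La France replicate 1, so they are not independent, and the SD of single pairs is not the error of their mean. Held-out pairs across slides ranged from 0.0837 to 0.149 with La France replicate 3 and from 0.042 to 0.658 with La France replicate 2. The held-out pairs therefore do not decide about slide. The 10 splits are too few for a share under 0.05: 1 split, the cultivars themselves, gave 2612 and the highest other 1753, and all 10 gave 0 probes past the adjusted p. A difference between the cultivars stays open too: apart from slide, limma gave 0 calls, and that test rests on 1 La France array.

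The replicate 3 arrays of Giant Laf and La France resembled each other (r = 0.9906) more than either resembled its own cultivar. For these arrays, brightness as the cause is argued against. After quantile normalization, over the brighter part of the probes, their correlation exceeded that of Giant Laf replicate 3 with its own cultivar by 0.00748. The SD over 10 random parts of the probes was 0.00149, which does not measure variation between arrays. Exchanged labels stay open: exchanging them lowered the probes at an unadjusted p below 0.05 from 2612 to 1024 but the within-minus-between correlation only from 0.00324 to 0.00281, and these arrays lie on different slides. A batch shared by these arrays cannot be told apart from other causes, since the labels name no batch. Their deviations from the cultivar means correlated at 0.133, while arrays of different numbers reached up to 0.191. The design gives no group that would mark them, so no biological explanation was tested.

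More probes were well above background in Giant Laf alone (30) than in La France alone (4), a share of 0.882 (exact binomial 95% interval 0.725 to 0.967, counting error only). With the same number of probes counted on every array, the share was 0.5 (0.319 to 0.681). Equal counts per array would also tend to level a true surplus of such probes in either cultivar. This share therefore cannot show whether brightness was the source of the imbalance. Another split of the arrays, that with the widest brightness gap, gave 111 such probes against 34 for the cultivars. Brightness did not follow cultivar throughout: the 75th percentile was 1336 on La France replicate 2, against 1202 and 1021 on Giant Laf replicates 2 and 3. In limma none of these 34 probes passed the adjusted threshold (smallest adjusted p = 0.256), which leaves a difference between the cultivars in them open.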
